A study of Homo sapiens with 18 samples.

How the data were processed

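The series profiled human osteosarcoma cells on Affymetrix human 3' expression arrays. MNNG/HOS (MNNG below) and 143B are established human osteosarcoma cell lines, and both carried the green fluorescent protein ZsGreen. The cells were loaded with PKH26, a membrane dye that is diluted as cells divide, and were grown as bone tumors in mice. Tumor cells that retained the dye (High, which the labels call tumor-initiating cells) were sorted apart from tumor cells that had lost it (Low). Per the labels' protocols, 150000 High and 700000 Low cells were sorted. The 18 arrays hold 4 MNNG_High, 4 MNNG_Low, 3 143B_High, 5 143B_Low and 2 MNNG_Lung samples, the last from lung metastases. Groups and tumor numbers were taken from the sample titles. The tumors are MNNG-1231, MNNG-1232, MNNG-1233 and MNNG-1235, and 143B-1251 to 143B-1255. The series design names 5 tumors per line, and a further MNNG tumor was not analysed here. The tumor numbers mark separate tumors. A pair of the 143B_High arrays each hold a pool of 2 tumors, 143B-51&52 and 143B-54&55, which were read as tumors 143B-1251 with 143B-1252 and 143B-1254 with 143B-1255. The lung arrays are from the animal numbered MNNG-1233 and a mixture whose makeup was not used here. Whether the lung cells were sorted is not given in the sources used here.

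The deposited values are log2 probe set signals that the authors made with RMA, per the submitters' processing notes. RMA corrects the background of each array, brings the arrays to one distribution by quantile normalization and summarises the probes of a probe set. Its version, the set of arrays normalized together and the genome build are not given in the sources used here. Quantile normalization can hide a change that most genes share. The deposited arrays still differed in spread. The interquartile range of the log2 signal was 2.09 and 2.28 on the lung arrays, 2.76 to 3.18 in MNNG_High and 3.29 to 3.4 in MNNG_Low. It was 3.26 to 3.34 in 143B_High and 3.3 to 3.48 in 143B_Low.

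The table holds 54675 probe sets. The platform annotation gave 1 gene to 41097 of them, several genes to 1801 and none to 11777, and no gene was named from the last 2 kinds. Symbols were compared through Entrez IDs with a RefSeq gene table of assembly GRCh38.p14, which held 19735 of the 19775 genes. None differed, and no coordinate was used. A gene was represented by its probe set with the highest mean signal. Genes reaching 5.36, the median of the table, on at least 3 arrays were kept, which left 14418 genes for testing. No detection call was used here, so a difference from a group whose mean lay under 5.36 gives a direction, and its size is uncertain.

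Differences were tested in R 4.3.3 with limma 3.58.1 on the log2 values. A single fit over all 18 arrays held a mean for each of the 5 groups, with Benjamini-Hochberg adjustment over genes and an adjusted p threshold of 0.05. There were 7 comparisons, namely High against Low within each line, their mean, their difference, the Low cells of 143B against those of MNNG, and the lung arrays against MNNG_Low and against MNNG_High. A count of called genes means genes past that threshold. Values written as a ± b are log2 differences with the standard error of the limma fit, unless SD is given. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over 30 lists. Of these, 21 hold pathways and functions and 9 hold markers of other cell types, and 511 of their 645 members were measured. The host is a mouse and the probes are human, so the marker lists can register host cells only by cross-hybridization. A dim member could pass the filter through the arrays where it was high, so the filter can favor a rise of a marker list in those groups. Single measures per array were compared by two-sided exact permutation tests, with adjustment over 24 tests.

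Named genes followed a rule. For each comparison these were the 10 called genes with the largest increase and the 10 with the largest decrease among those whose groups did not overlap, with up to 4 members of smallest p for each list described. The comparisons, tests, lists, rule and most alternatives were fixed before the data were examined. The position of an array was computed after the data were seen, as the projection of its difference from the Low mean of its own line onto the difference between the lung arrays and MNNG_Low over the 14418 genes, in percent.

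Tumor numbers pair High and Low arrays of the same tumor. Deviations from the group means of same-numbered MNNG arrays correlated with r of 0.494, 0.370, 0.299 and 0.579 over genes, and in 143B r was 0.542 for tumor 143B-1253. The pool 143B-51&52 had r of -0.192 with Low 143B-1251 and 0.529 with Low 143B-1252, and the pool 143B-54&55 had r of 0.243 with Low 143B-1254 and 0.063 with Low 143B-1255. That second pool had its highest r, 0.259, with Low 143B-1251, a tumor not assigned to it. High and Low arrays of different tumors had r of -0.471 to 0.202 in MNNG and -0.339 to 0.259 in 143B. These values do not settle which tumors the pools hold. The sample descriptions carry 3 date tags. Tag 1 covers the MNNG_Low arrays of tumors MNNG-1232, MNNG-1233 and MNNG-1235, tag 2 covers Low MNNG-1231, all 4 MNNG_High and both lung arrays, and tag 3 covers all 143B arrays. Alternatives covered the tumor as a block, the date tag, the arrays in the fit, array weights, a second quantile normalization, median centring, the filter, the choice of probe set (with the types _x_at and _s_at, whose probes can match several transcripts, left out), a 3' to 5' covariate and leaving out each array in turn.

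The fit was tested on simulated data for 14418 genes with 200 changed. In the MNNG comparison 88.1% of genes with a log2 change of 1 were recovered and 32.8% of those with 0.5, in the 143B comparison 85.1% and 16.4%, in the comparison of the lines 91.0% and 40.3%, and in the lung comparison 64.2% and 17.9%. Every simulated array had the spread of the bone tumor groups. The real lung arrays correlated less (0.865, against 0.956 or more within bone tumor groups), so the lung shares hold for a smaller spread than the data have. The number of arrays limits the precision.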

Results

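Transcript levels were measured in dye-retaining (High) and dye-diluted (Low) tumor cells from orthotopic bone tumors of 2 human osteosarcoma lines. MNNG gave 4 High and 4 Low arrays and 143B gave 3 High and 5 Low arrays, and 2 further arrays came from MNNG lung metastases. Within a bone tumor group, arrays correlated with r of at least 0.956 over all probe sets, and the lung arrays correlated with each other at 0.865. The mean log2 signal was between 5.74 and 5.77 on every array.

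The comparison of MNNG_High with MNNG_Low asked which transcripts mark the dye-retaining fraction of these tumors. CELF2, an RNA-binding splicing regulator, was 14.3-fold higher in MNNG_High (3.83 ± 0.29, n = 4 and 4, adjusted p = 1.18e-06). CXCL14, a chemokine, was 5.94-fold higher (2.57 ± 0.36, adjusted p = 0.00128). AIF1, a calcium-binding protein of macrophages, was 5.06-fold higher (2.34 ± 0.27) and IGF1, a growth factor, 4.14-fold higher (2.05 ± 0.27). CADM1, a cell adhesion molecule, rose by 2.30 ± 0.39, and the ubiquitin ligase gene RNF5 rose by 3.02 ± 0.36. Some genes of the dividing cell went the other way, with the mitotic kinase gene BUB1 at -0.79 ± 0.15 and the spindle protein gene DLGAP5 at -0.78 ± 0.15. They belong to a mitosis list with 13 of 28 members lower, not called with an estimated correlation (camera adjusted p = 0.565).

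The largest increases also took in TMEFF2 (2.23 ± 0.61), a transmembrane protein, and CPEB4 (2.22 ± 0.21), a regulator of translation. They held the small GTPase CDC42 (2.14 ± 0.25) and ZEB2 (1.97 ± 0.29), a transcription factor of the epithelial-mesenchymal transition. Probe sets disagreed for several of these. Of the 5 probe sets tested for CDC42, 1 rose and 1 fell, and of the 3 for ZEB2, 2 rose and 1 fell. For CELF2, 3 of 4 rose, with differences from 0.48 to 3.83. Among the 10 largest decreases were AFG2A (-1.43 ± 0.24), SLAIN1 (-1.36 ± 0.23), a microtubule-associated protein, the NADH pyrophosphatase gene NUDT12 (-1.31 ± 0.20), the mitochondrial fission gene GDAP1 (-1.29 ± 0.27), the noncoding RNA DLEU2 (-1.26 ± 0.19), and SUDS3 (-1.24 ± 0.26). The others were PTGR2 (-1.23 ± 0.22), a prostaglandin reductase, GPM6B (-1.22 ± 0.17), TRAPPC13 and IFT74 (-1.21 ± 0.25), an intraflagellar transport protein. The lower group of TMEFF2, AFG2A, NUDT12 and PTGR2, and both groups of SLAIN1, had a mean under the filter value of 5.36, so the sizes are uncertain there.

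**Figure D1:**
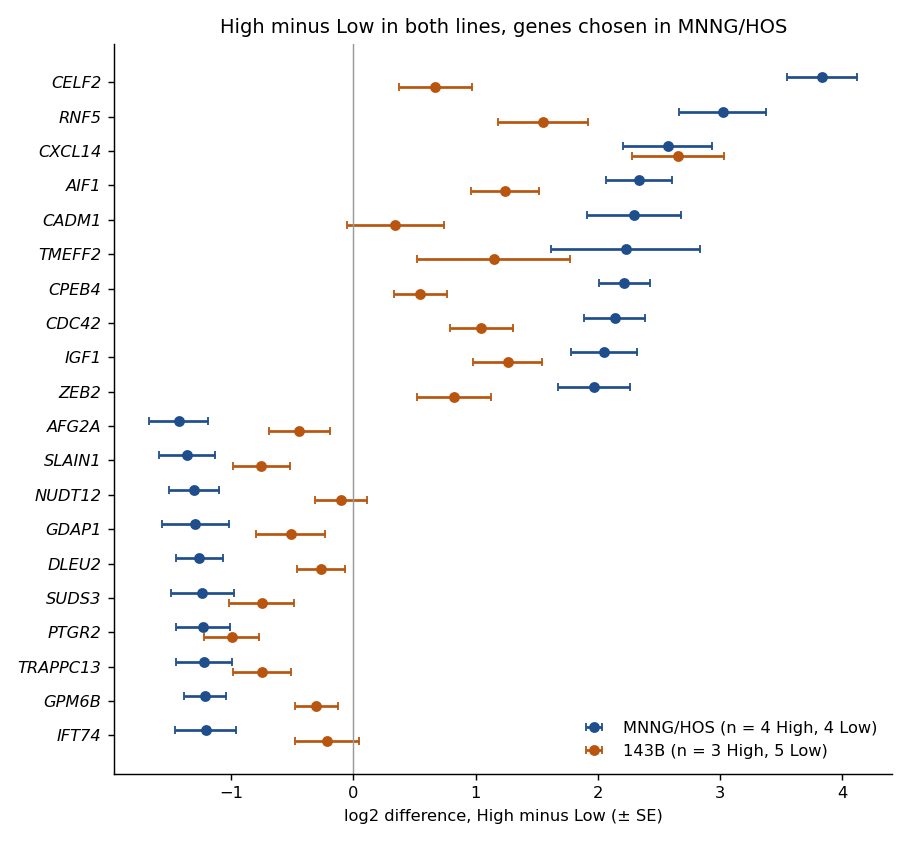
Log2 difference, High minus Low, with its standard error for the 20 genes named by rule in MNNG, shown for MNNG (4 High and 4 Low arrays) and 143B (3 High and 5 Low arrays). CXCL14 differed by 2.57 in MNNG and 2.65 in 143B, while CELF2 differed by 3.83 in MNNG and 0.67 in 143B.

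Mitosis genes fell as a group in MNNG_High. Of 28 members 13 were lower and none higher, and 16 were lower when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.000598, and adjusted p = 0.565 with an estimated correlation). KIF20A, a mitotic kinesin, was at -0.85 ± 0.17 and CDKN3, a cyclin-dependent kinase phosphatase, at -0.79 ± 0.15. DNA replication and S phase genes fell too, with 13 of 27 lower and 1 higher. There were 16 lower and 1 higher adjusted over the list alone, and camera adjusted p = 0.00452 (adjusted p = 0.565 with an estimated correlation). UNG, which removes uracil from DNA, was at -0.48 ± 0.12, GMNN, an inhibitor of replication licensing, at -0.58 ± 0.14, and the helicase subunit genes MCM3 and MCM2 at -0.51 ± 0.13 and -0.54 ± 0.14.

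Macrophage and myeloid markers rose in MNNG_High, with 5 of 11 members higher and none lower, and 7 higher adjusted over the list alone (camera adjusted p = 0.000159, and adjusted p = 0.0489 with an estimated correlation). The call at an estimated correlation was lost without the lung arrays (0.186) and with the tumor as a block (0.467). Beside AIF1 these held SPI1 (1.65 ± 0.28), the transcription factor of myeloid cells, FCER1G (0.88 ± 0.18), an Fc receptor chain, and C1QA (0.62 ± 0.15), a complement subunit. ATP6V0D2, a proton pump subunit of osteoclasts, rose by 1.95 ± 0.21. Marker lists of neutrophils (2 of 3 higher, 3 adjusted over the list alone), skeletal muscle (2 of 8, and 2) and lung epithelium (2 of 7, and 4) rose as well, with none lower, each with camera adjusted p = 0.0380 and adjusted p = 0.426 with an estimated correlation. They included CSF3R (0.54 ± 0.16), the granulocyte growth factor receptor, LTF (0.59 ± 0.17), lactoferrin, ACTN3 (0.60 ± 0.15) and ACTA1 (0.59 ± 0.17) of muscle, and LAMP3 (0.64 ± 0.20) and SFTPC (0.39 ± 0.12), a surfactant gene. Both groups of LTF and LAMP3 and the Low group of FCER1G, C1QA and ACTN3 had a mean under the filter value. Only 3 of 11 neutrophil, 8 of 17 muscle and 7 of 13 lung epithelium members passed the filter. Dim members could pass it through the arrays where they were high, so the rise of these lists is partly tied to the filter. These 3 lists were not called without High MNNG-1233 (adjusted p = 0.0565). The neutrophil and lung epithelium lists were not called without Low MNNG-1233 (0.0537), and the muscle list not without High MNNG-1235 (0.0722). After a second quantile normalization the macrophage and mitosis lists were called (adjusted p = 0.00612 and 0.00615). The DNA replication, neutrophil and lung epithelium lists (0.143) and the muscle list (0.220) were not. The neutrophil, muscle and lung epithelium lists were not called with the GAPDH 3' minus 5' signal (0.0756, 0.0910 and 0.104), the hybridization control level (0.241, 0.0514 and 0.192) or the position (0.970, 0.280 and 0.970) as a covariate, of which the last 2 also leave out the lung arrays.

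Stem cell and tumor-initiating cell markers did not shift as a list in MNNG_High (camera adjusted p = 0.938, and adjusted p = 0.945 with an estimated correlation). Of 23 members, 2 were higher and 3 lower, and 1 higher and 2 lower adjusted over the list alone. STAT3, a transcription factor of cytokine signaling, was at 0.57 ± 0.17 and the embryonic transcription factor SALL4 at 0.50 ± 0.18, while ALDH1A3, an aldehyde dehydrogenase, was at -0.73 ± 0.23 and MCAM, an adhesion molecule, at -0.59 ± 0.15. With the probe sets of types _x_at and _s_at left out STAT3 was at -0.35 and MCAM at 0.49. The median and mean of this list were -0.07 and -0.15 while camera gave an upward direction, and such a difference in sign between median, mean and test occurred for 13 of the 30 lists.

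In all, 3761 of 14418 genes were called between MNNG_High and MNNG_Low, 1532 higher and 2229 lower. Of these 144 differed by more than 2-fold, 65 higher and 79 lower. The groups did not overlap for 2748 of the called genes and for 29.8% of all genes, where chance gives 2.86%. The median of all genes was -0.186. With the tumor as a block, fitted without the lung arrays, 8044 genes were called, 5670 with array weights, 1547 with the GAPDH 3' minus 5' signal as a covariate, 2317 with only these groups in the fit, 6407 with the lung arrays left out, and 3 with the date tag as a covariate. Within date tag 2, where 1 Low array remained and is assumed to vary like the other groups, 0 were called (limma, 353 genes at an unadjusted p under the threshold). In the fit of all arrays 6257 had such a p. Without one array the count was 1376 (without High of tumor MNNG-1231), 1676 (High MNNG-1233), 5939 (High MNNG-1235), 2257 (Low MNNG-1231), 2420 (Low MNNG-1232), 1673 (Low MNNG-1233) and 2175 (Low MNNG-1235). The block also called cholesterol synthesis genes (-0.36, camera adjusted p = 0.0407, against 0.0541 for the same arrays without it). Oxidative phosphorylation genes (-0.34, 0.00193) and erythroid markers (0.32, 0.0456) were called with it too, but also without it once the lung arrays were left out (0.000408 and 0.0447). With the block each had adjusted p = 0.556 with an estimated correlation. The split of higher and lower calls moved with the scaling, to 744 and 284 after a second quantile normalization and to 989 and 3721 after median centring. With the median of all probe sets brought to the same value on every array, mitosis genes lay at a mean of -0.62, DNA replication genes at -0.48 and macrophage markers at 0.57. Relative to the median of all genes, without that step, they lay at -0.33, -0.19 and 0.87. The gene groups gave a mean of -0.65 for mitosis, -0.49 for DNA replication and 0.61 for macrophage markers both with the date tag as a covariate and within tag 2. Both settings compare MNNG_High with Low MNNG-1231 alone, so they are 1 estimate that rests on 1 Low array. The neutrophil, muscle and lung epithelium lists rest on that array there too, so these settings decide nothing about their calls.

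In 143B the same comparison called 1 gene, CXCL14, which was 6.30-fold higher in 143B_High (2.65 ± 0.38, n = 3 and 5, adjusted p = 0.0194). AIF1 was at 1.24 ± 0.28, C1QA at 0.46 ± 0.15 and the collagen gene COL3A1 at 1.44 ± 0.41, and WIF1, a secreted Wnt inhibitor, at -0.95 ± 0.20. These did not pass (adjusted p = 0.358, 0.721, 0.577 and 0.296). Mitosis genes shifted upward, opposite to MNNG, with a mean of 0.23 (camera adjusted p = 2.57e-05, and adjusted p = 0.376 with an estimated correlation). None of the 28 passed over all genes, 3 were higher adjusted over the list alone and 24 lay above 0. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was at 0.68 ± 0.16, the kinase gene AURKA at 0.53 ± 0.14 and CDK1 at 0.58 ± 0.17, and AURKA was at -0.29 with the probe sets of types _x_at and _s_at left out.

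Immediate early and heat shock genes had 21 of 25 members above 0 in 143B_High, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 2.57e-05, and adjusted p = 0.382 with an estimated correlation). JUND, an AP-1 subunit, was at 0.50 ± 0.16 and ZFP36, which destabilizes cytokine mRNAs, at 0.74 ± 0.24. Macrophage markers had 0 of 11 called and 3 higher adjusted over the list alone (camera adjusted p = 0.000406, and adjusted p = 0.103 with an estimated correlation). Hypoxia genes (adjusted p = 0.0172), inflammatory genes (0.0172), and markers of lung epithelium (0.0170), endothelium (0.0346) and osteoclasts (0.0470) also shifted upward, and cholesterol synthesis genes downward (0.0164). For these the estimated correlation gave adjusted p = 0.584 for hypoxia and 0.376 for the others. Members were ANGPTL4 (0.71 ± 0.28), NFKBIA (0.42 ± 0.20), FOXJ1 (0.53 ± 0.16), PECAM1 (0.28 ± 0.17) and ATP6V0D2 (0.73 ± 0.22), and for cholesterol synthesis HMGCS1 (-0.46 ± 0.21). None of their members passed over all genes, and 1 lung epithelium and 1 osteoclast member were higher adjusted over the list alone.

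Of 14418 genes 745 had an unadjusted p under the threshold in 143B. With array weights 201 genes were called, 89 higher and 112 lower, and 9 with only these groups in the fit. With the tumor as a block 7 genes were called and the endothelial list was not (adjusted p = 0.0558). The block added osteoblast genes (0.18, adjusted p = 0.0434, against 0.0718 for the same arrays without it). Oxidative phosphorylation (-0.12, 0.0081) and Notch genes (0.13, 0.03) were called with it and also without it once the lung arrays were left out (0.00433 and 0.0391). With the block and an estimated correlation the 3 lists had adjusted p = 0.372, 0.586 and 0.502. CXCL14 was no longer called without High 143B-1253 (2.24, adjusted p = 0.383), High 143B-51&52 (2.87, 0.0592), High 143B-54&55 (2.85, 0.0678), Low 143B-1252 (2.52, 0.0664) or Low 143B-1254 (2.46, 0.0610). It was also not called after a second quantile normalization (2.55, 0.0720), with the hybridization control level as a covariate (2.23, 0.413) or with the mean over probe sets (1.04, 0.282). Without any one of these 5 arrays, and after the second normalization, 0 genes were called (limma, 411 to 774 at an unadjusted p under the threshold). Without Low 143B-1255 2 genes were called. Without High 143B-1253 the hypoxia (adjusted p = 0.114), inflammatory (0.297), endothelial (0.352) and osteoclast lists (0.139) were not called. Without Low 143B-1251 the inflammatory (0.141), endothelial (0.0691) and osteoclast lists (0.137) were not. The same held without Low 143B-1252 for the hypoxia (0.0528) and endothelial lists (0.0540), and without Low 143B-1255 for the hypoxia (0.0833) and osteoclast lists (0.0845). It also held without High 143B-54&55 for the cholesterol (0.0540), osteoclast and lung epithelium lists (0.0640). The osteoclast (0.0677) and lung epithelium lists (0.0638) were not called after a second quantile normalization, nor the cholesterol (0.0591) and lung epithelium lists (0.0601) with the GAPDH 3' minus 5' signal as a covariate. With the hybridization control level as a covariate the cholesterol (0.642), macrophage (0.610), endothelial (0.740), osteoclast (0.178) and lung epithelium lists (0.850) were not called. The endothelial, osteoclast and lung epithelium lists were not with the position (0.338, 0.119 and 0.119), and the endothelial and osteoclast lists not without a filter (0.166 and 0.0953). The osteoclast list was also lost without the lung arrays (0.0651), which the control level and position fits leave out as well, so its loss there is not settled by the covariate.

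**Figure D2:**
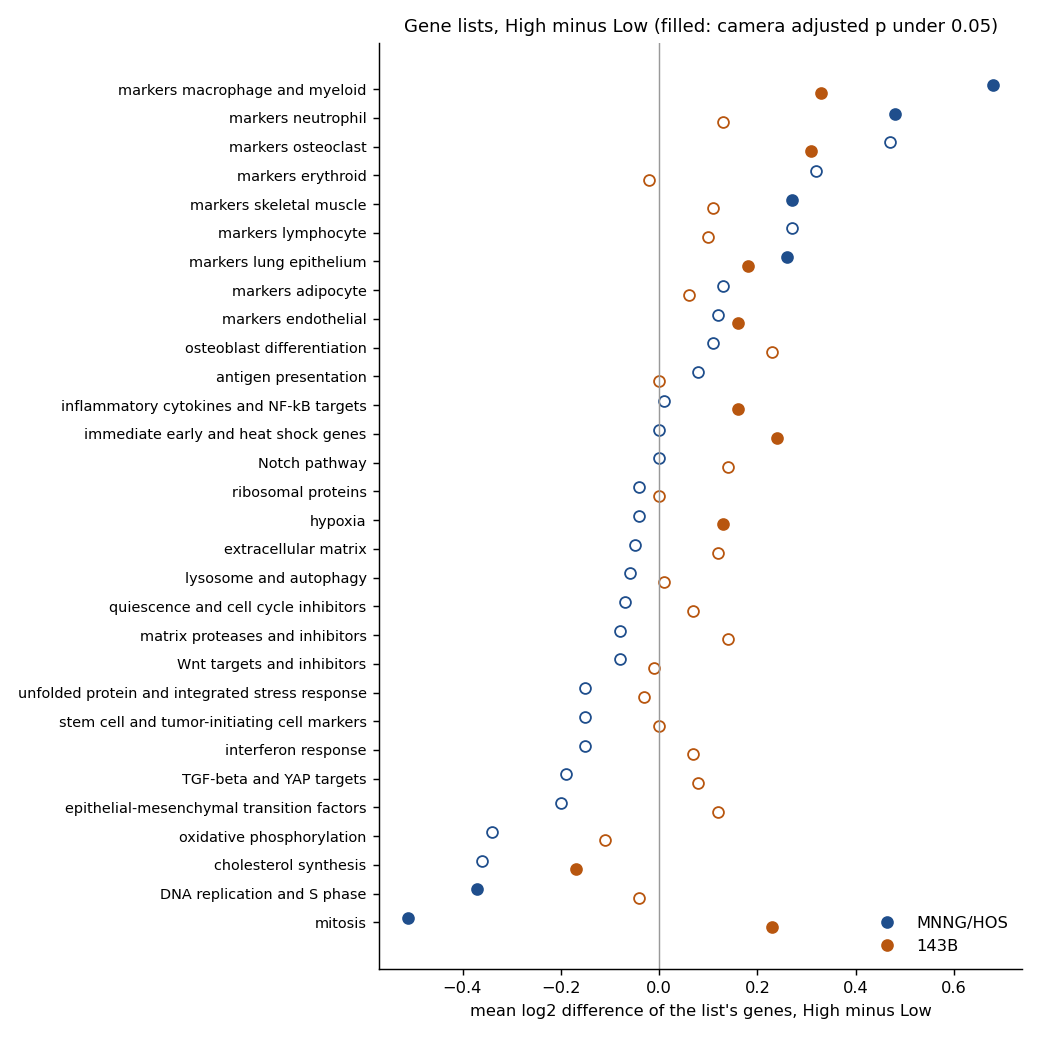
Mean log2 difference, High minus Low, over the measured genes of each of the 30 lists in MNNG and 143B, with filled points for lists past a camera adjusted p of 0.05 at the preset correlation. Macrophage and myeloid markers lay above 0 in both lines (0.68 and 0.33), and mitosis genes lay at -0.51 in MNNG and 0.23 in 143B.

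Averaged over both lines, High cells carried more CXCL14 (2.61 ± 0.26, adjusted p = 6.34e-05, n = 7 High and 9 Low), RNF5 (2.29 ± 0.26), CELF2 (2.25 ± 0.21), AIF1 (1.79 ± 0.19), IGF1 (1.66 ± 0.20), CDC42 (1.59 ± 0.18) and the matrix glycoprotein THBS4 (1.53 ± 0.22). CDC42 was at -0.22 with the probe sets of types _x_at and _s_at left out. PTGR2 fell by 1.11 ± 0.16, SLAIN1 by 1.06 ± 0.16 and EVI5, a regulator of mitotic progression, was at -0.90 ± 0.15. Macrophage markers rose with 4 of 11 higher, 4 adjusted over the list alone (camera adjusted p = 9.4e-05, and adjusted p = 0.0409 with an estimated correlation). The latter was 0.175 without the lung arrays and 0.456 with the tumor as a block. Immediate early genes rose with 3 of 25 higher and 2 adjusted over the list alone (adjusted p = 0.0420, and adjusted p = 0.806 with an estimated correlation), among them NR4A2 (0.65 ± 0.18), an orphan nuclear receptor, and JUND (0.51 ± 0.11).

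DNA replication genes fell in the mean of the lines with 7 of 27 lower and 1 higher, and 11 and 1 adjusted over the list alone (adjusted p = 0.0285). Cholesterol synthesis genes fell with 6 of 19 lower and 1 higher, and 7 and 1 adjusted over the list alone (adjusted p = 0.0420). Both lists had adjusted p = 0.585 with an estimated correlation, and with the GAPDH 3' minus 5' signal as a covariate neither was called (0.0897 and 0.102). ACAT2, which makes acetoacetyl-CoA, was at -0.51 ± 0.11 and HMGCS1, the synthase after it, at -0.56 ± 0.15, while MVK, mevalonate kinase, was at 0.35 ± 0.10. Markers of lung epithelium (3 of 7 higher, 3 adjusted over the list alone, adjusted p = 0.0285), skeletal muscle (2 of 8, 3 over the list alone, adjusted p = 0.0402) and neutrophils (0 of 3, 3 over the list alone, adjusted p = 0.0466) shifted upward, with adjusted p = 0.319, 0.319 and 0.514 with an estimated correlation. In this mean 2505 genes were called, 1085 higher and 1420 lower. There were 6281 called and the neutrophil list not (adjusted p = 0.0625) with the tumor as a block, 5756 with array weights, 809 with the GAPDH signal as a covariate, and 47 called with the date tag as a covariate. The neutrophil list was already lost when the lung arrays were left out (0.0553), as they are in the block. The block added osteoclast markers (0.37, 0.0424, against 0.0660 for the same arrays without it), and oxidative phosphorylation genes were called with it (-0.23, 0.00139) and without it once the lung arrays were left out (0.000276). With the block and an estimated correlation these had adjusted p = 0.544 and 0.560. The lung epithelium, muscle and neutrophil lists were not called with the GAPDH signal (0.0897, 0.0897 and 0.0922), the hybridization control level (0.309, 0.178 and 0.860) or the position (0.537, 0.192 and 0.955) as a covariate. The cholesterol list was not with the control level (0.256) or the position (0.178), the immediate early list not without a filter (0.147), and the neutrophil list not without High MNNG-1231 and MNNG-1233 (0.0523). With the date tag the cholesterol list had adjusted p = 0.0694. The count was 1064 without High 143B-1253, 937 without High 143B-54&55, and 1484 without Low 143B-1254. It was 1357, 1612 and 4560 without High MNNG-1231, MNNG-1233 and MNNG-1235, and 1414 and 1665 without Low MNNG-1233 and MNNG-1235. After a second quantile normalization the DNA replication, muscle (0.220), cholesterol, neutrophil (0.148) and lung epithelium lists (0.0989) were not called. Higher and lower calls numbered 416 and 201 after a second quantile normalization and 694 and 2559 after median centring. The macrophage list alone was called without every single array. The DNA replication, cholesterol, neutrophil and muscle lists were not called without High MNNG-1235 (adjusted p = 0.0609) and the lung epithelium and immediate early lists not either (0.0504 and 0.0726). Without High MNNG-1232 the DNA replication, cholesterol and neutrophil lists (0.0605) and the immediate early list (0.0834) were not. The immediate early list was also lost without Low 143B-1251 (0.0741), High 143B-51&52 (0.0506), Low MNNG-1231 (0.0655) or Low MNNG-1235 (0.0512). The neutrophil list was lost without High 143B-51&52 (0.0506), Low MNNG-1231 (0.0643), Low MNNG-1233 (0.0556) or Low MNNG-1235 (0.0508), and the cholesterol list was lost without Low MNNG-1235 (0.0512).

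The difference between the lines was itself tested. CELF2 was the 1 gene called (-3.16 ± 0.41, 143B minus MNNG, adjusted p = 0.0061), with 1449 genes at an unadjusted p under the threshold. Its signal was already 9.47 ± 0.24 (SD, n = 5) in 143B_Low and 10.14 ± 0.22 (SD, n = 3) in 143B_High, against 7.09 ± 0.62 in MNNG_Low and 10.92 ± 0.62 in MNNG_High (SD, n = 4 each). Mitosis genes differed, with all 28 members above 0, 17 of them passing adjusted over the list alone and 0 over all genes, and a mean of 0.74 (camera adjusted p = 2.93e-13, and adjusted p = 0.222 with an estimated correlation). AURKB, a kinase of chromosome segregation, differed by 0.94 ± 0.23 and AURKA by 0.97 ± 0.20, and AURKA was at -0.22 with the probe sets of types _x_at and _s_at left out. DNA replication genes (0.33, adjusted p = 0.00312), macrophage markers (-0.35, adjusted p = 0.00312) and erythroid markers (-0.34, adjusted p = 0.0149) differed as lists with 0 members passing over all genes or over the list alone. With an estimated correlation these had adjusted p = 0.519, 0.222 and 0.519. GMNN was at 0.57 ± 0.20, AIF1 at -1.10 ± 0.39 and SLC4A1, an erythrocyte anion exchanger, at -0.45 ± 0.20.

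With the tumor as a block 5 genes were called for the difference between the lines, 234 with array weights, and with the date tag as a covariate 0 (limma, 660 at an unadjusted p under the threshold), where CELF2 was at -2.35 (adjusted p = 0.749) and the erythroid list had adjusted p = 0.118. CELF2 was also not called with the mean over probe sets (-1.17, adjusted p = 0.176) or with the probe sets of types _x_at and _s_at left out (-0.87, 0.476). After a second quantile normalization the mitosis list alone was called (mean 0.51), with adjusted p = 0.0816 for DNA replication and 0.0579 for macrophage and erythroid markers. The erythroid list was not called without a filter (0.0883), and with the position as a covariate it and the macrophage list were not (0.889 and 0.255), nor was CELF2 (-2.56, 0.142). The erythroid list was also not called without High 143B-1253 (adjusted p = 0.0750) or High MNNG-1233 (0.0849). Across all genes the High minus Low differences of the 2 lines correlated with Pearson's r = 0.61 and Spearman's rho = 0.63, with no shared arrays, and genes are not independent replicates. Of the 3761 genes called in MNNG, 88.0% had the same sign in 143B, against 73.4% of all genes.

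Measures of the arrays also separated High from Low. The interquartile range of the signal averaged 2.96 in MNNG_High and 3.34 in MNNG_Low without overlap (exact permutation p = 0.0286, adjusted p = 0.0858). In 143B it averaged 3.29 in High and 3.39 in Low (exact permutation p = 0.125). Bacterial hybridization controls, which are added at one concentration to every array, read 11.68 ± 0.75 (SD, n = 4) in MNNG_High and 10.45 ± 0.06 (SD, n = 4) in MNNG_Low (exact permutation p = 0.0286). They read 11.42 ± 0.21 (SD, n = 3) in 143B_High and 10.27 ± 0.51 (SD, n = 5) in 143B_Low (exact permutation p = 0.0179). Each is the smallest p of its design, and both had an adjusted p of 0.0858 over 24 tests. The 3' minus 5' signal of GAPDH was 0.59 ± 0.11 (SD, n = 4) in MNNG_High and 0.38 ± 0.04 (SD, n = 4) in MNNG_Low without overlap (exact permutation p = 0.0286, adjusted p = 0.0858). In 143B it was 0.76 ± 0.25 (SD, n = 3) and 0.65 ± 0.16 (SD, n = 5, adjusted p = 0.522). That of ACTB went the other way, at 1.13 ± 0.33 and 1.57 ± 0.15 (SD) in MNNG_High and MNNG_Low (exact permutation p = 0.0857) and 1.64 ± 0.41 and 2.12 ± 0.43 (SD) in 143B (exact permutation p = 0.196), so these controls settle no difference in RNA quality. MNNG_High lay at 19.3%, 9.4%, 22.3% and 4.8% of the way from Low to lung (tumors MNNG-1231, MNNG-1232, MNNG-1233 and MNNG-1235) and 143B_High at 4.6%, 2.6% and 4.8%. With the MNNG_High arrays of tumors MNNG-1231 and MNNG-1233 left out, chosen after their positions were seen, 56 genes were called in MNNG (1537 with the lung arrays left out of the fit as well). The mitosis mean was -0.45 and the macrophage mean 0.54 (camera adjusted p = 9.54e-06 and 1.99e-05). The neutrophil, muscle and lung epithelium lists were not called (0.0851, 0.0795 and 0.0908). CELF2 was then at -2.72 for the difference between the lines (adjusted p = 0.0631), and the macrophage and erythroid lists were not called for it (0.0518 and 0.289).

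**Figure D3:**
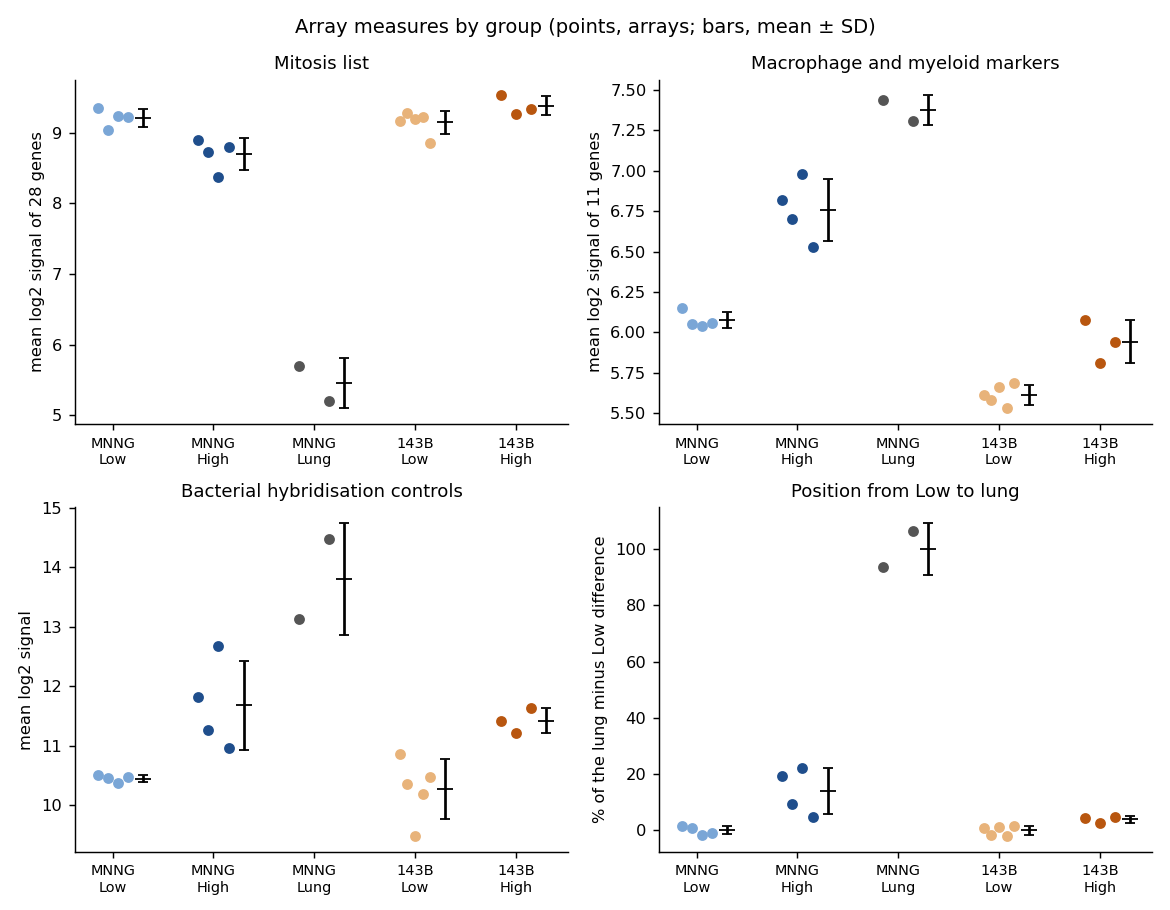
Mean log2 signal of 28 mitosis genes, 11 macrophage and myeloid markers and the bacterial hybridization controls, and the position from Low to lung in percent, for each array by group, with group mean and SD. The 4 MNNG_High arrays lay below the 4 MNNG_Low arrays for mitosis (8.90 or less against 9.04 or more) and above them for the controls (10.97 or more against 10.50 or less).

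The comparison of 143B_Low with MNNG_Low describes the 2 lines. MMP1, interstitial collagenase, was at least 165-fold higher in 143B (9.02 ± 0.28, n = 5 and 4, adjusted p = 5.3e-14), CCND2, cyclin D2, at least 27.6-fold (5.98 ± 0.18) and EPB41L3, a membrane skeleton protein, at least 18.3-fold (6.60 ± 0.20). These folds are taken against the filter value of 5.36, because the MNNG_Low means (3.71, 4.17 and 2.96) lay under it. MNNG in turn had more SCG5 (-6.31 ± 0.29), a secretory granule protein, LXN (-6.08 ± 0.18), a carboxypeptidase inhibitor, HNMT (-6.05 ± 0.23), which inactivates histamine, and EDIL3 (-5.93 ± 0.43), an integrin ligand. The 143B_Low means of SCG5, LXN and HNMT (4.89, 3.35 and 3.32) lay under the filter value too, and against it the folds were at least 57.1, 16.6 and 16.1. DNA replication genes were higher in 143B for 13 of 27 members, 17 adjusted over the list alone, with CDC6, a replication licensing factor, at 1.12 ± 0.12 and RRM1, ribonucleotide reductase, at 1.13 ± 0.14 (camera adjusted p = 0.000141, and adjusted p = 0.608 with an estimated correlation). Antigen presentation genes were higher for 7 of 15, 8 adjusted over the list alone, with the immunoproteasome gene PSMB9 at 3.01 ± 0.24 and the peptide transporter genes TAP1 and TAP2 at 1.22 ± 0.14 and 1.04 ± 0.13 (camera adjusted p = 0.00193, and adjusted p = 0.586 with an estimated correlation).

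Other genes that set 143B apart were PDZRN3 (5.68 ± 0.40), RTN1 (5.58 ± 0.13), CHRNA1 (5.45 ± 0.19), an acetylcholine receptor subunit, TMEM47 (5.34 ± 0.18), UBE2QL1 (4.99 ± 0.25), the survival gene BCL2A1 (4.91 ± 0.24) and PASD1 (4.89 ± 0.15). MNNG had more GALC (-5.31 ± 0.20), a lysosomal galactosidase, SELENOP (-4.97 ± 0.67), a selenium carrier, KHDRBS3 (-4.89 ± 0.30), NPTX2 (-4.87 ± 0.51), MAP9 (-4.83 ± 0.41) and LAPTM5 (-4.77 ± 0.23). The lower group of each of these 13 genes had a mean under the filter value (3.11 to 5.34), so the sizes have no settled order, and against that value the folds were at least 6.57 to 31.5. In all 4158 genes were called, 2074 higher and 2084 lower, of which 1421 differed by over 2-fold. The groups did not overlap for 3862 of them and for 38.3% of all genes, where chance gives 1.59%. With the date tag as a covariate the DNA replication and antigen presentation lists were at a mean of 0.33 and 0.67. That setting leaves Low MNNG-1231 as the only MNNG_Low array compared. Since every 143B array carries tag 3 and no MNNG array does, the line and that tag cannot be told apart.

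The lung arrays differed from MNNG_Low in 12541 genes, 5064 higher and 7477 lower, and 10422 of these by over 2-fold. BNIP3, a mitophagy receptor, was at -7.24 ± 0.23 (n = 2 and 4, adjusted p = 1.03e-14), LAMB1, a laminin chain, at -6.90 ± 0.27, FERMT2, an adaptor of integrin adhesion, at -6.87 ± 0.33 and BCAT1, an aminotransferase, at -6.85 ± 0.27. Their lung means (4.67 to 5.14) lay under the filter value, against which they were at least 126, 73.8, 86.6 and 98.8-fold lower. Genes of basic cell function fell together. Mitosis genes were lower for 27 of 28 and higher for 1 (median -3.90), oxidative phosphorylation genes lower for 26 of 27 (median -4.23) and ribosomal protein genes lower for 21 of 22 (median -3.06), with the same counts adjusted over the list alone (camera adjusted p = 3.43e-05, 7.06e-05 and 0.00319, and adjusted p = 0.367, 0.367 and 0.504 with an estimated correlation). RPL3 was at -3.31 ± 0.15, RPS3 at -3.38 ± 0.23, NDUFA9, a complex I subunit, at -4.41 ± 0.18 and DLGAP5 at -5.76 ± 0.18 (lung mean 3.86, under the filter value).

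Markers of other cell types were higher on the lung arrays, by medians of 1.96 for macrophages (10 of 11 higher, 1 lower), 2.02 for neutrophils (3 of 3), 1.39 for lymphocytes (6 of 7), 1.36 for endothelium (7 of 8), 1.38 for skeletal muscle (7 of 8), 1.35 for lung epithelium (6 of 7) and 1.21 for erythroid cells (5 of 5), with the same counts adjusted over the list alone and camera adjusted p between 0.00679 and 0.0245 (adjusted p = 0.367 each with an estimated correlation). C1QA was at 2.36 ± 0.18, CD8A, a T cell coreceptor, at 2.70 ± 0.26, HBB, a globin chain, at 2.57 ± 0.24, TNNI2, a muscle troponin, at 2.02 ± 0.15 and SFTPC at 1.80 ± 0.15. LAPTM5 was the macrophage member that fell (-4.14 ± 0.29). RNF5 (5.31 ± 0.44), CELF2 (5.27 ± 0.35), ATP6V0D2 (5.02 ± 0.26), the potassium channel gene KCNA3 (4.42 ± 0.29), PLK3 (4.13 ± 0.23), NFIA (4.01 ± 0.24) and THRA (3.69 ± 0.21), a thyroid hormone receptor, were among the 10 largest increases. The MNNG_Low means of C1QA, CD8A, TNNI2, KCNA3 and NFIA lay under the filter value, so their sizes are uncertain. Both lung arrays count toward the filter, so dim marker genes that were high on them passed it more easily. With an estimated correlation 0 lists were called (camera, 2 at an unadjusted p under the threshold).

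**Figure D4:**
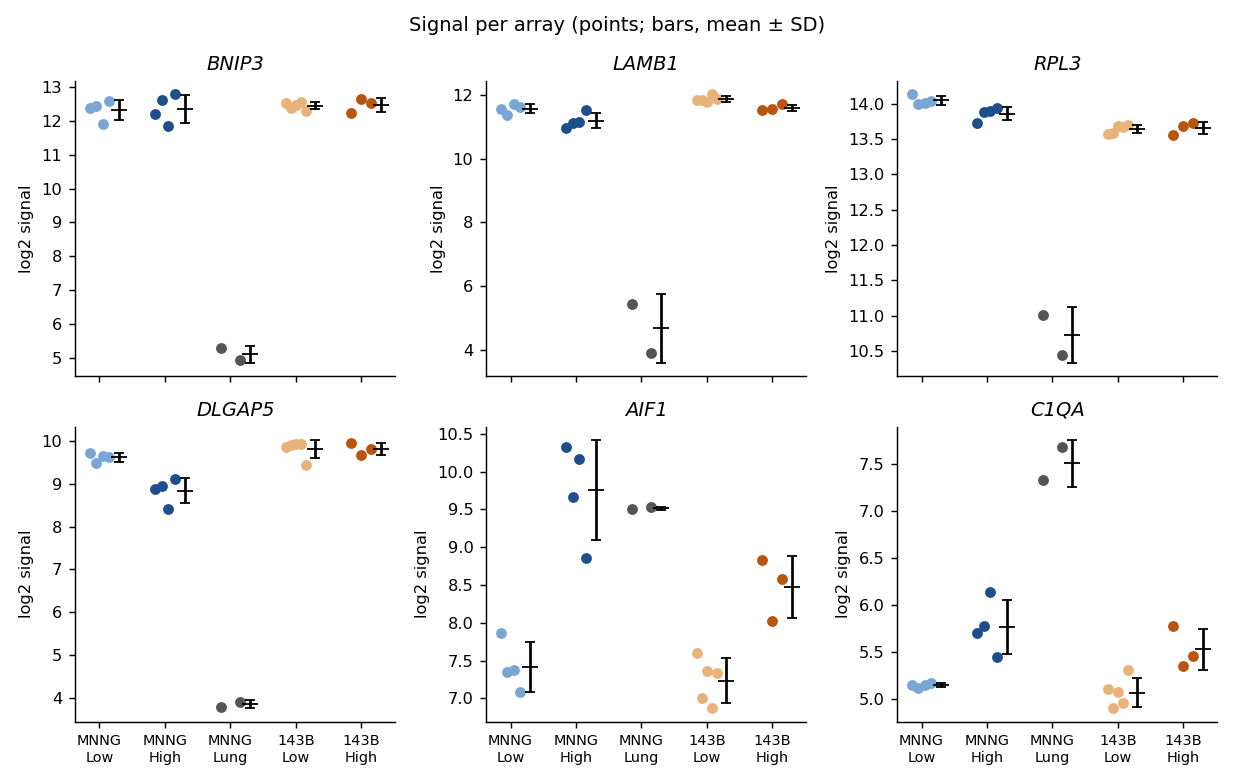
Log2 signal of 6 genes on each array by group, with group mean and SD. BNIP3, LAMB1, RPL3 and DLGAP5 lay lower on both lung arrays than on every bone tumor array, and C1QA lay higher.

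Hypoxia genes were lower on the lung arrays for 24 of 29 (median -3.89, camera adjusted p = 0.000676, and adjusted p = 0.367 with an estimated correlation), with P4HA1, a collagen prolyl hydroxylase, at -5.58 ± 0.18 (lung mean 5.30, under the filter value). DNA replication genes were lower for 24 of 27 and higher for 1 (median -3.14, adjusted p = 0.000208), extracellular matrix genes for 20 of 28 with 2 higher (median -3.89, adjusted p = 0.0170), and unfolded protein response genes for 19 of 25 with 2 higher (median -3.02, adjusted p = 0.0124). The same held of immediate early genes for 21 of 25 with 2 higher (median -2.65, adjusted p = 0.0146), TGF-beta and YAP targets for 18 of 24 with 2 higher (median -2.76, adjusted p = 0.0331) and lysosome genes for 17 of 21 with 3 higher (median -2.81, adjusted p = 0.0335). With an estimated correlation adjusted p was 0.539 for immediate early genes and 0.367 for the others. Counts adjusted over the list alone were the same. After a second quantile normalization the unfolded protein (adjusted p = 0.137), immediate early (0.287), TGF-beta (0.111) and lysosome lists (0.192) were not called. Neither were the neutrophil, erythroid and muscle (0.0571) and lung epithelium markers (0.0566). The TGF-beta list was also lost with the date tag as a covariate (0.0511).

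Against MNNG_High the lung arrays differed in 11879 genes, 5021 higher and 6858 lower, and 17 lists were called, 7 upward and 10 downward, with none called at an estimated correlation (smallest adjusted p = 0.334) and 7 lists called after a second quantile normalization. The unfolded protein and TGF-beta lists (adjusted p = 0.0975), the immediate early (0.169), lysosome (0.116), macrophage (0.0697) and lymphocyte lists (0.0557), the neutrophil and lung epithelium lists (0.0719) and the erythroid and muscle lists (0.0812) were lost there. The neutrophil list was also lost with the tumor as a block (0.0524). The erythroid call was not kept without the lung array of MNNG-1233 (mean 1.003), which leaves 1 lung array. HBE1, an embryonic globin, was at 3.86 ± 0.48 (n = 2 and 4, adjusted p = 6.79e-07), SH3TC1 at 2.85 ± 0.22 and TSPAN7 at 2.74 ± 0.37, while BNIP3 (-7.27 ± 0.23) and PRNP (-6.82 ± 0.41), the prion protein gene, were lower. The lower group of TSPAN7, BNIP3 and PRNP had a mean under the filter value. Bacterial controls read 13.14 and 14.47 on the lung arrays, and the probe set of the human Alu repeat read 14.45 and 13.36, against 14.57 to 14.99 on the bone tumor arrays. The groups of 2 and 4 allow no exact permutation p under 0.0667. The limma p-values and standard errors of both lung comparisons measure only the spread within groups, pooled over all arrays of the fit, most of them from bone tumors. The lung arrays correlated less with each other (0.865) than arrays within bone tumor groups (0.956 or more). Their SD was 1.75 for PRNP and 0.25 for BNIP3, against 0.28 and 0.42 in MNNG_High. The standard errors can thus be too small for genes that vary more between the lung arrays. The groups did not overlap for 85.7% of all genes against MNNG_Low, where chance gives 13.33%, and the median of all genes was -0.639. After a second quantile normalization 6074 genes were higher and 6388 lower against MNNG_Low. The difference of MNNG_High from MNNG_Low correlated across genes with that of the lung arrays from MNNG_Low at r = 0.76, where unchanged groups simulated against the shared Low arrays gave 0.41, and the covariance was 0.735 against 0.017. With the Low arrays split 2 and 2, r was 0.70 to 0.73. Calls shared in direction were 1516 higher and 2147 lower, where independent lists give 538.1 and 1155.9, a value that leaves out the shared Low arrays. The unchanged groups simulated against shared arrays gave 0 and 0 shared calls (limma, 68.7 and 69.9 at an unadjusted p under the threshold in both). No gene was changed in that simulation, so calls near 0 were fixed in advance and give no baseline for the shared calls. Its lung arrays also had the spread of the bone tumor groups, which is smaller than in the data. With the Low arrays split 2 and 2, shared calls were 75 to 483 higher (independent lists, 26.3 to 166.5) and 28 to 936 lower (14.8 to 509). The 143B difference, which shares no array with the lung comparison, correlated with it at r = 0.47 and rho = 0.53.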

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

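The tests of explanations in the 3 patterns weighed here were chosen only after the result was seen, and the tests of the difference between the lines were fixed earlier.

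Between High and Low 3761 genes were called in MNNG and 1 in 143B (5670 and 201 with array weights), and MNNG_High lay on average 13.95% of the way from Low to lung. These counts do not measure a difference in effect between the lines, since the direct test of it called 1 gene. The differences of the lines correlated at r = 0.61. Of the genes called in MNNG, 88.0% had the same sign in 143B, against 73.4% of all genes. Array brightness cannot be told apart, since High and Low do not overlap in hybridization control level (with it as a covariate the median size over the called genes went from 0.59 to 0.36, the median SE from 0.15 to 0.19 and the calls from 6407 to 2). MNNG_High and MNNG_Low also did not overlap in interquartile range (2.76 to 3.18 against 3.29 to 3.4). The same held of the poly-A minus hybridization control signal (-2.09 to -1.23 against -3.42 to -2.23). In 143B these differed by -0.1 and 0.03, and neither can be told apart in MNNG. The date tag cannot be told apart either, since 1 Low array shares the tag of MNNG_High (slope of the difference from that array 0.95, against 0.95, 1.09 and 1.01 for the arrays of tag 1). Some RNA of the kind on the lung arrays may contribute, but it cannot be told apart from array spread. Of the 882 genes over 4-fold higher on the lung arrays, 84.6% were also higher in 143B_High, with no shared arrays. This held for 51.1% of 1942 genes within 0.5 log2 units on the lung arrays, which were not matched for signal level. A narrower spread raises dim genes too, and both the lung arrays and 143B_High had a lower mean interquartile range than the Low arrays of their line. The number of sorted cells cannot be told apart either, since the protocols give 150000 High and 700000 Low cells. A difference between dye-retaining and dye-diluted cells, which the design names, stays open and was not tested apart from these.

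The lung arrays lacked transcripts abundant in MNNG_Low, with BNIP3, LAMB1 and 81.8% of the 1969 genes at 10 or more in MNNG_Low over 4-fold lower. Degraded RNA cannot be told apart, because its controls disagree: the 3' minus 5' signal of ACTB averaged -2.56 on the lung arrays (-2.16 and -2.97) against 1.57 in MNNG_Low, and that of GAPDH was 0.45 and 0.94 against 0.34 to 0.41. A low share of human tumor RNA may contribute, since ribosomal protein genes had a median of -3.06 and markers of 7 other cell types rose. The probe set of the human Alu repeat fell much less, by 0.8 on average. It read 14.45 and 13.36 on the lung arrays against 14.57 to 14.8 in MNNG_Low, so the human readouts differ in size. The arrays are labelled as ZsGreen-transduced tumor cells. Neither the makeup of the mixture nor whether the lung cells were sorted is given in the sources used here. The lung arrays also had a narrower spread, with a lower quartile of 4.5 and 4.64 against 3.85 to 3.88 in MNNG_Low. A narrower spread lowers bright genes and raises dim ones whatever they encode, so these shifts cannot tell the 2 apart. With an estimated correlation camera gave adjusted p = 0.504 for the ribosomal list and 0.367 for each marker list. After a second quantile normalization the neutrophil, erythroid, muscle and lung epithelium lists were not called. A difference between metastases and bone tumors, which the design names, stays open as untested.

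Mitosis genes moved apart in the lines, by -0.51 in MNNG and 0.23 in 143B (per tumor -0.45, -0.31, -0.87 and -0.42 in MNNG, and 0.33, 0.04 and 0.29 in 143B). One linear effect of brightness in both lines would move the list alike in them, because the hybridization controls rose by 1.24 and 1.15. For the same reason their level as a covariate could change the difference between the lines little. It was 0.74 without the covariate and 0.73 ± 0.16 with it (16 arrays), so that fit adds no support. An effect of brightness in each line stays open. Array spread stays open too, since the interquartile range differed by -0.38 in MNNG and -0.1 in 143B. For RNA as on the lung arrays the position gives -0.15 in 143B, where the list rose (exact permutation p = 0.0179 after this amount was taken off, and 0.0714 before). That amount was scaled on log2 values, which need not hold for mixed RNA, and the permutations ignore the tumors. Such RNA is therefore not excluded in 143B. In MNNG the position gives -0.52 on average but -0.73, -0.35, -0.84 and -0.18 per tumor, and -0.27 against a shift of -0.45 without High MNNG-1231 and MNNG-1233, so its share cannot be told apart (-0.30 ± 0.20 with it as a covariate, 16 arrays). The date tag cannot be told apart either, with the highest MNNG_High mean at 8.9 against 9.35 on the 1 Low array of the same tag. A difference in division between the cells stays open as untested.

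The effects of the lines differed by test for the mitosis list (0.74), DNA replication (0.33), macrophage markers (-0.35), erythroid markers (-0.34) and CELF2 (-3.16). With an estimated correlation the lists had adjusted p = 0.222, 0.519, 0.222 and 0.519, and CELF2 had 0.749 with the date tag as a covariate. Control signals outside the gene comparisons were higher than in Low. Hybridization controls were higher by 1.24 in MNNG_High, 1.15 in 143B_High and 3.36 on the lung arrays, and poly-A controls, which are added to the RNA before labeling, by 2.59, 1.19 and 5.57. The poly-A minus hybridization control signal was higher by 1.36 in MNNG_High (exact permutation p = 0.0286, adjusted p = 0.0858). It was higher by 0.03 in 143B_High (exact permutation p = 0.911) and 2.21 on the lung arrays (exact permutation p = 0.0667). The cause was not tested.

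Of 349 groups of 4 or 5 values examined for an array far from the others, 18 had one, where chance gives 17.4. In 143B_Low these were the mitosis mean of 143B-1255 (8.86, others 9.17 to 9.28), NFKBIA (12, others 10.96 to 11.08) and EVI5 (8.99) on the same array, LXN of 143B-1251 (3.73) and PTGR2 of 143B-1253 (6.02). In MNNG_High they were FCER1G (6.43), SLC4A1 (7.68) and COBL (4.40) of MNNG-1233, CPEB4 of MNNG-1231 (11.10), AURKB of MNNG-1232 (6.73) and STAT3 of MNNG-1235 (8.68). In MNNG_Low they were the poly-A controls of MNNG-1231 (8.27, others 7.05 to 7.14) with BMP2 (4.83) and FCER1G (5.01) on the same array, JUND (12.11) and SALL4 (5.66) of MNNG-1232, and COL1A2 (7.53) and EGR1 (12.32) of MNNG-1235.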

How the results depend on the processing

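Alternatives that left out the lung arrays or the High arrays of tumors MNNG-1231 and MNNG-1233, took the hybridization control level or the position as a covariate, held the lung arrays in the block, or took an estimated correlation without the lung arrays or with the block, were chosen after seeing the data; the others were fixed earlier. MNNG, 143B, mean, difference and Low stand for the genes called in MNNG_High against MNNG_Low (3761), 143B_High against 143B_Low (1), their mean (2505), their difference (1) and 143B_Low against MNNG_Low (4158). Where no reason is given the cause was not tested.

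Without the lung arrays 6407 genes were called in MNNG, 1 in 143B, 4938 in the mean, 1 in the difference and 5361 in Low. With the tumor as a replicate block, also without them, 8044 genes were called in MNNG (2622 higher, 5422 lower), 7 in 143B, 6281 in the mean and 5 in the difference, and with the pooled Low arrays averaged 7849, 8, 5285 and 3. As a random block the tumor gave 3933 in the mean and 2 in the difference. At the preset correlation and over the same arrays, the block ended the call of the endothelial list in 143B and of oxidative phosphorylation in the difference (0.0147 to 0.0523) and added 1 list in MNNG, 2 in 143B and 1 in the mean. It could not be estimated for the comparison of the lines, which share no tumor. With the lung arrays in the fit, where 1 of them shares a tumor with bone arrays, the block gave 12228 and 11429 genes against Low and High and ended the call of the neutrophil list against High (adjusted p = 0.0524). Fitting only the groups compared gave 2317 in MNNG, 9 in 143B, 4938 in the mean and 6529 in Low, and array weights 5670, 201, 5756 and 7024 with 234 in the difference.

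The date tag as a covariate left 3 genes in MNNG, 47 in the mean, 0 in the difference and 1594 in Low, and within date tag 2, which leaves 1 Low array, 0 genes (limma, 353 at an unadjusted p under the threshold) and 10 lists were called in MNNG. With either setting Low MNNG-1231 is the only MNNG_Low array compared. Over the arrays without lung, the hybridization control level left 2, 0 and 0 genes in MNNG, 143B and the mean, with 2 in the difference and r = 0.405 between the lines, and the position 3, 2, 4 and 6529 (Low). Without the High arrays of MNNG-1231 and MNNG-1233 the counts were 56 in MNNG, 497 in the mean and 0 in the difference with 2 lists and r = 0.497, and with the lung arrays left out too 1537 in MNNG, 0 in the difference and r = 0.497. The 3' to 5' covariate gave 1547, 2 and 809 in MNNG, 143B and the mean, with 3 lists in the mean.

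A second quantile normalization gave 1028, 0 and 617 genes in MNNG, 143B and the mean, and 2, 3 and 1 lists in MNNG, the mean and the difference, and 9 and 7 on the lung arrays against Low and High. No filter gave 10 lists in MNNG and 4 in Low, and a filter at 7.08, which tests fewer genes, gave 2385, 1578, 8283 and 7883 genes in MNNG, the mean and both lung comparisons. All probe sets gave 3 and 3917 in 143B and the mean. An estimated correlation left 1 list in MNNG and 1 in the mean, the macrophage list in both, and 0 in 143B, the difference, Low and both lung comparisons. Without the lung arrays, and with the block, it left 0 in MNNG, 143B, the mean and the difference (camera, 2, 4, 5 and 2 at an unadjusted p without them and 1, 2, 2 and 1 with the block), where the macrophage list had adjusted p = 0.186 and 0.175, and 0.467 and 0.456, in MNNG and the mean. The mean over probe sets gave 0 in the difference and turned STAT3 (-0.093) and TOB1 (-0.083) in MNNG and ATF3 (0.086) on the lung arrays, and leaving out types _x_at and _s_at gave 0 in 143B and the difference and turned CDC42 (-0.46 in MNNG, -0.22 in the mean), MCAM (0.49), STAT3 (-0.35), AURKA (-0.29 in 143B, -0.22 in the difference, 1.31 on the lung arrays) and ATF3 (2.09), since other probe sets then stand for the gene. The position turned CSF3R (-0.051) and SALL4 (-0.10).

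Leaving out single arrays gave 1376 to 5939 genes in MNNG, 0 to 2 in 143B, 937 to 4560 in the mean, 1 to 4 in the difference, 3445 to 3768 in Low, 12274 to 12430 and 11555 to 11981 on the lung arrays against Low and High. Lists ranged over 3 to 8, 5 to 12, 1 to 10, 3 to 4, 2 to 3, 17 to 18 and 16 to 17 in that order, and r from 0.534 to 0.643. Of the values for single genes and lists, 6109 kept their direction and side of the threshold, 797 kept direction and lost the call, 12 gained it and 13 reversed. For the other counts of 0 genes, limma gave 433 at an unadjusted p for 143B after the second normalization, 630 without types _x_at and _s_at and 1125 with the control level. It gave 1456 for the mean with the control level. For the difference it gave 660 with the date tag, 1379 and 1126 for the choices of probe set, and 707 and 1559 without the High arrays of MNNG-1231 and MNNG-1233. For the other counts of 0 lists camera gave 2 or 3 at an unadjusted p. How far signal over background limits the calls was not tested.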

Other observations

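Genes of matrix breakdown, stemness and bone formation set the Low cells of the 2 lines apart without a shift of their lists. Beside MMP1, 143B had more of the plasminogen activator gene PLAU (2.50 ± 0.16, n = 5 and 4) and its receptor PLAUR (1.71 ± 0.14), and MNNG had more MMP13 (-2.23 ± 0.23), a collagenase. The protease list had 7 of 20 members higher and 5 lower (camera adjusted p = 0.490). PROM1, a surface marker of stem cells, was higher in 143B (4.29 ± 0.18), as was LIN28B (3.39 ± 0.34), an inhibitor of let-7 microRNAs, while NES, an intermediate filament of progenitors, was lower (-3.86 ± 0.27). Of 23 stem cell markers 9 were higher and 5 lower (adjusted p = 0.693). The bone morphogenetic protein gene BMP2 was higher (3.47 ± 0.25) and RUNX2, the osteoblast transcription factor, and COL1A2 lower (-1.67 ± 0.21 and -2.32 ± 0.38), with 4 of 15 osteoblast genes higher and 5 lower (adjusted p = 0.927). Matrix genes split as well, with COL8A1 (4.31 ± 0.21) higher and COL5A1 (-3.11 ± 0.25) lower, 8 of 28 members higher and 9 lower (adjusted p = 0.927). Interferon genes had 4 of 23 higher and 8 lower (adjusted p = 0.714), with ISG20 at 2.39 ± 0.26 and IFI44 at -3.06 ± 0.27. Wnt genes had 6 of 18 higher and 0 lower (adjusted p = 0.0810), among them WIF1 (3.83 ± 0.18), WNT5A (1.67 ± 0.19) and CCND1 (1.32 ± 0.21). The lower group of MMP13, PROM1, LIN28B, COL8A1, IFI44 and WIF1 had a mean under the filter value of 5.36, so their sizes are uncertain.

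In MNNG_High, quiescence and cell cycle inhibitor genes did not shift as a list (2 of 19 higher and 2 lower, camera adjusted p = 0.758). BTG1, an antiproliferative gene, was at 0.72 ± 0.14 (n = 4 and 4) and RB1, the retinoblastoma gene, at -0.65 ± 0.15. TOB1 was at 0.44 ± 0.14 and RBL2 at -0.36 ± 0.13, and TOB1 had the other sign with the mean over probe sets. Epithelial-mesenchymal transition genes had 1 of 15 higher and 4 lower (adjusted p = 0.496), with OCLN, a tight junction protein, at -0.90 ± 0.22, KRT19, an epithelial keratin, at -0.70 ± 0.21 (High mean 4.85, under the filter value) and TWIST2 at -0.45 ± 0.15. PTH1R, the parathyroid hormone receptor of osteoblasts, was at 0.90 ± 0.18, with 2 of 15 osteoblast genes higher and 0 lower (adjusted p = 0.494).

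The numbers of called genes and lists were compared with other splits of the same arrays, a test fixed earlier. For MNNG the real split gave the most genes of 35 splits (1 split as large, 3761 against at most 76 otherwise), which excludes chance only over splits that ignore the tumors. The 8 splits that part all 4 tumors gave at most 0 genes apart from the real one and are too few for a share under 0.05. The 24 that part 2 tumors gave at most 12 and the 3 that part none at most 76. Its 6 called lists were reached by 11 of 35 splits (at most 10 otherwise) and by 4 of the 8 that part all tumors, so chance cannot be excluded for the list count. For 143B, 5 of 56 splits gave as many genes as the real 1 (at most 1 otherwise) and 6 of 56 as many lists as the real 9 (at most 12), so chance cannot be excluded for either. The 18 splits of 143B that part all 3 tumors, of which the others gave at most 0 genes and 8 lists, are too few for a share under 0.05. For the mean of both lines 1 of 100 splits gave as many genes (2505 against at most 1), which excludes chance only over splits that ignore the tumors. For lists 20 of 100 gave as many (7, at most 10), so chance cannot be excluded. The 17 splits of both lines that part all tumors, of which the others gave at most 1 gene and 6 lists, are too few as well. For the difference between the lines 4 of 100 splits gave as many genes as the real 1, with 960, 245 and 5 in the others. These 4 were the splits that grouped the MNNG arrays as High and Low or the mirror of it, and the other 96 gave at most 0. The calls thus follow the structure of the MNNG samples under several groupings of 143B, and of the 17 splits that part all tumors 2 gave as many, so chance is not excluded for a difference between the lines. Of the splits 48 of 100 gave as many lists (4, at most 13), so chance cannot be excluded for lists. For 143B_Low against MNNG_Low 1 of 100 splits gave as many genes (4158 against at most 2273), which excludes chance. That largest other split was the line split with 1 array, Low 143B-1253, moved to the MNNG group, so it follows the lines. Of the splits 68 of 100 gave as many lists (2, at most 8), so chance cannot be excluded for lists.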
